A study of Mus musculus with 56 samples.

How the data were processed

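RNA was sequenced from the front paws of 56 male DBA/1 mice in 5 groups. Per the labels' protocols, total RNA was isolated with a Qiagen RNeasy kit, libraries were made with the Illumina TruSeq Stranded mRNA kit, and paired-end reads were taken on an Illumina NovaSeq system. The submitters' processing notes name DESeq2 without a version. The aligner, the genome build, the annotation and whether strand was used in counting are not given in the sources used here. The deposited values are FPKM (fragments per kilobase of transcript and M mapped fragments, where M stands for mega), 1 column per library. This unit was read from the values, since no header states it. The table holds 53431 features, of which 52244 are Ensembl genes and 1187 are miRBase hairpins. Symbols were found for 52207 of the Ensembl identifiers, and 51027 identifiers matched GENCODE M21 (GRCm38) including the version. Coordinates are given on that build for matching identifiers.

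Depth is not stated per library. Single-exon genes of at least 400 bases have low FPKM values that step in multiples of what 1 fragment is worth, and these steps put the depth at 39.9 to 54.8 M fragments (mean 46.9 ± 3.61, SD, n = 56). With a tolerance of 0.05 of a step, 70.9% to 76.4% of the low values were whole multiples, so whole counts could not be rebuilt for every gene. Mean depth was 46.0 ± 2.47 M fragments in the 4 libraries without arthritis and 45.7 ± 3.14 M in the 13 isotype libraries. No pair of libraries held identical values, and the highest correlation between libraries was 0.993.

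The design fixed before the data were examined assumed counts. Because the file held FPKM rather than counts, the test named for that case was used: limma 3.58.1 in R 4.3.3, with a trended and robust prior, on log2(FPKM + 1). All 56 libraries entered 1 fit with a mean per group and 51 residual degrees of freedom. Features with a mean FPKM of at least 1 in any group were tested, which left 14700 genes and 0 hairpins. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over these genes, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Errors of fold changes are standard errors, and errors of levels are standard deviations between mice.

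Gene lists for 35 cell types and pathways of the paw were written before the data were examined. Each library's score was the mean log2(FPKM + 1) of the list's members, in place of the log2 CPM first foreseen. Score differences were tested by permuting libraries, exactly where a group had 4 to 7 libraries and with 100000 resamples otherwise, and were adjusted over the 35 lists of a comparison. Camera, a set test of limma, served as the alternative. A list of 20 circadian clock genes was written after the gene results were seen, and its score is the mean of 10 genes driven by the clock's activators (Dbp, Tef, Hlf, Per1, Per2, Per3, Nr1d1, Nr1d2, Ciart and Bhlhe41) minus the mean of 5 in antiphase (Arntl, Clock, Npas2, Nfil3 and Cry1). Treated groups were also compared with mice without arthritis for list scores, which was added after the data were seen.

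Genes named in the text follow a rule fixed beforehand for comparisons with calls. It takes the 6 genes of the list of drug targets and receptors, the 5 highest and 5 lowest fold changes among called genes with enough signal and a proper symbol, and for each list that moved its 3 called members with the smallest p. Comparisons without calls show drug targets and also Dbp, Tef, Rtp4 or Spon2. These were chosen, after the results were seen, from genes named in other comparisons. Oas1a has close paralogs and C4b a near-identical neighbour, so reads shared between copies make their values uncertain, and reads of overlapping or antisense genes could have been counted together.

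The gene test and the list test were tried on simulated data before use. Among 200 of 14700 genes changed by a log2 of 1, 93.8% were recovered between anti-TNF and isotype and 86.1% between isotype and no CIA. For a log2 of 0.5 the shares were 75.9% and 56.2%. The list test recovered 86% of lists shifted by 1 between anti-TNF and isotype and 40% between isotype and no CIA.

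The alternatives tried were pseudocounts of 0.1 and 10, no filter, fits of the compared groups alone, covariates for tissue scores, and leaving out each library in turn. A further covariate was the index run, which is 1 of 5 stretches of index numbers in the titles within which mouse numbers ascend, except that isotype replicate 10 (mouse 52) is out of order in run 3. After the data were seen, median-of-ratios scaling, a weight per library, leaving out the 2 least correlated libraries, covariates for the clock and neutrophil scores, and list tests without each isotype library were added. Replicate numbers follow the order of deposition and pair no mice. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 ran the permutation tests and figures.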

Results

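Whole front paws were profiled by RNA sequencing in collagen-induced arthritis (CIA), a mouse model in which immunisation with chicken type II collagen, here on days 1 and 21, leads to autoimmune joint inflammation. From day 21 the immunised mice received antibody injections 2 times a week for 5 weeks. These were an isotype control at 30 mg/kg (13 mice), an antibody against TNF at 30 mg/kg (clone XT3.11, 13 mice), an antibody against IL-6 at 10 mg/kg (clone MP5-20F3, 13 mice), or both antibodies (13 mice, the combination group). The no CIA group held 4 mice. RNA was taken on day 91, after the injections had ended. A group named as under an antibody had received it earlier and was not being dosed when paws were taken. Each library is a separate mouse, and estimated depth ran from 39.9 to 54.8 M fragments. The largest axis of variation held 42.7% of the variance between libraries, and 14.0% of that axis lay between groups.

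The comparison of isotype with no CIA mice asked which genes differ in paws with CIA. The isotype mice had been immunised and injected with the control antibody, so the groups differ in more than joint inflammation. Genes induced by interferon were higher in isotype paws. Rtp4, a receptor transport protein induced by interferon, had an FPKM of 11.2 ± 6.98 (SD, n = 13) in isotype paws against 2.29 ± 0.620 (n = 4) without CIA, a log2 difference of 1.75 ± 0.308 (SE, limma adjusted p = 0.00534). Oasl2 and Oas1a, of the oligoadenylate synthetase family that senses viral RNA, were higher by 1.77 ± 0.332 and 1.74 ± 0.318, and Isg15, a ubiquitin-like modifier, by 1.55 ± 0.321 (adjusted p = 0.00534, 0.00534 and 0.0157). Usp18, the protease that removes Isg15 from proteins, was higher by 0.94, and Lgals3bp, a secreted galectin-binding glycoprotein, by 1.46 (adjusted p = 0.00534 and 0.0411). Per2, a repressor of the circadian clock, was the single gene that was lower, at 1.495 ± 0.515 against 3.95 ± 1.48 FPKM (log2 -0.97 ± 0.193, adjusted p = 0.0108). For Rtp4, Oasl2, Oas1a, Isg15, Usp18 and Lgals3bp every isotype library lay above every library without CIA. For a gene chosen beforehand 1 of 2380 splits gives this order, but these genes were chosen for their difference, so it is no test of them. On GRCm38, Rtp4 (ENSMUSG00000033355.6) lies on chromosome 16 (23520291 to 23614222), Oasl2 on chromosome 5 (114896936 to 114912234) and Per2 on chromosome 1 (91415982 to 91459324).

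In all, limma called 22 genes higher and 1 lower of 14700 tested between isotype and no CIA. Scaling the libraries by median of ratios changed the split to 48 higher and 19 lower. With pseudocount 10, which damps genes with low values, it turned to 1 higher and 4 lower, and 2 of the 23 genes were still called. It was 61 and 5 with pseudocount 0.1, 21 and 14 with no filter, 20 and 15 with the compared groups alone, 62 and 14 with muscle and epidermis scores as covariates, and 44 and 5 without the 2 least correlated libraries. With a weight per library it was 1016 and 546. The count rested on few mice without CIA: it was 0 without no CIA replicate 4, 8 without no CIA replicate 1, 8 without no CIA replicate 2, 15 without isotype replicate 9 and 59 without isotype replicate 5. Across the 17 fits that left out a library, Rtp4, Oas1a and Usp18 were called in 16, Oasl2 and Per2 in 15, Isg15 in 14 and Lgals3bp in 7, with an adjusted p of 0.246 for Lgals3bp without no CIA replicate 4. With the clock gene score as a covariate it was 0 (546 at an unadjusted p under 0.05), with the neutrophil score 11, and with index run as a covariate, which rests on 2 isotype libraries sharing a run with no CIA, 2744. Clock scores of isotype and no CIA paws differed by -0.71 (exact permutation p = 0.0118, adjusted p = 0.0131), and in run 1 by -1.13 (2 against 4 libraries).

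Of the 35 gene lists, 7 had higher scores in isotype than in no CIA paws. The interferon response list differed most clearly, with a score difference of 0.97 (2.27 ± 0.417 against 1.30 ± 0.0966, exact permutation p = 0.00042, the smallest that 2380 splits can give, adjusted p = 0.0147). Of its 23 measured members 10 were called higher over all genes and 21 adjusted over the list alone, and the groups did not overlap. Monocyte and macrophage markers were higher by 0.81, genes responding to TNF and NF-kB by 0.79, complement genes by 0.67, class II antigen presentation genes by 0.62, T cell markers by 0.42 and mast cell markers by 0.33 (exact permutation adjusted p = 0.0462, 0.0462, 0.0462, 0.0221, 0.0392 and 0.0462). No member of these 6 lists was called over all genes. Adjusted over the list alone, 8 of 20 monocyte and macrophage markers, 11 of 21 TNF and NF-kB response genes, 8 of 13 complement genes, 9 of 13 class II genes, 0 of 9 T cell markers and 3 of 10 mast cell markers were higher. With an estimated correlation between genes, camera gave adjusted p = 0.114 for the interferon list and adjusted p = 0.427 for each of the other 6. Leaving out 1 isotype library at a time kept the interferon and class II calls in 13 of 13 tests, monocyte and macrophage markers in 6, complement genes in 6, T cell markers in 7, TNF and NF-kB response genes in 5 and mast cell markers in 4. The number of lists was 2 without isotype replicate 3, 7, 9, 10, 11 or 13, 3 without replicate 12, 17 without replicate 5 and 12 without replicate 8. Leaving out a no CIA library ended list calls: 0 lists were left without replicate 1, 3 or 4 and 4 without replicate 2, while the interferon difference stayed at 0.93 or above. This says little about the lists themselves, since 3 libraries against 13 make 560 splits, whose smallest p of 0.00179 adjusts to 0.0625 for a single list. Within the single index run that held both groups, 2 isotype libraries had a mean interferon score of 2.99 and the 4 no CIA libraries 1.30. These 2, isotype replicates 4 and 7, also had the highest neutrophil scores of the isotype group (3.76 and 3.50).

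Several lists with large differences did not pass the correction. Matrix-degrading enzymes and their inhibitors differed by 1.29, fibrillar matrix genes by 1.25, mature neutrophil markers by 1.11 and osteoblast markers by 1.10 (exact permutation adjusted p = 0.0611, 0.0611, 0.0611 and 0.0850). Adipocyte markers differed by -0.44 and skeletal muscle markers by -0.63 (adjusted p = 0.0787 and 0.443, exact permutation test). Neutrophil scores spread from 1.11 to 3.76 among isotype mice and from 1.11 to 1.28 among mice without CIA. The 6 genes of the antibody targets and their receptors were not called. Il6 had an FPKM of 1.89 ± 2.50 in isotype paws and 0.0469 ± 0.0638 without CIA (log2 1.06 ± 0.600, limma adjusted p = 0.343), and Tnf 1.65 ± 0.567 and 0.913 ± 0.120 (log2 0.44 ± 0.250, adjusted p = 0.345).

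**Figure D1:**
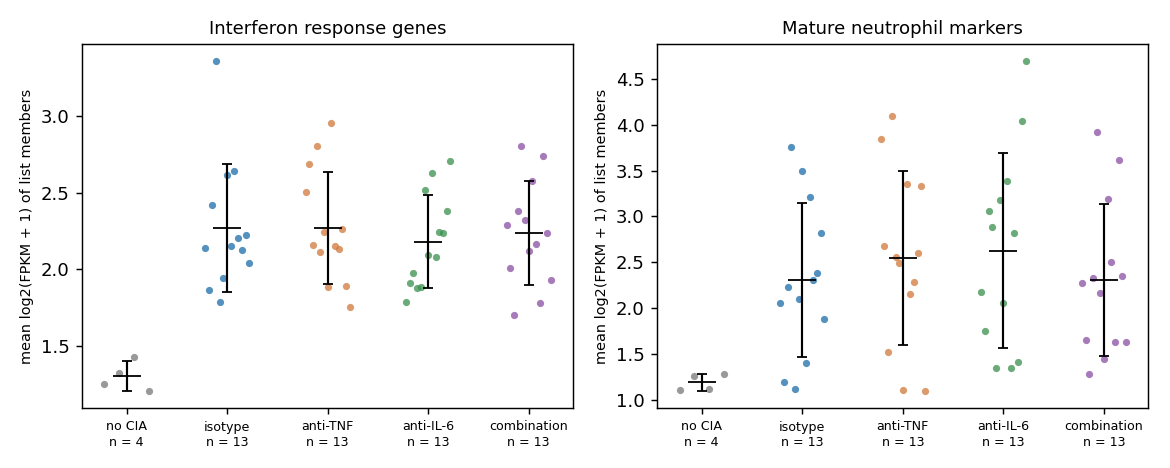
Scores of interferon response genes (left) and mature neutrophil markers (right) per library, as mean log2(FPKM + 1) of list members, in the 5 groups; points are mice and bars the mean ± SD. Interferon scores of all 52 mice with CIA lie above those of the 4 mice without, which reach 1.43.

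TNF blockade against isotype asked what the antibody changed in arthritic paws. No gene passed the test. Tnf itself had 2.19 ± 1.45 FPKM under anti-TNF and 1.65 ± 0.567 under isotype (log2 0.18 ± 0.172, limma adjusted p = 0.979), and Il6 had 1.499 ± 2.20 and 1.89 ± 2.50 (log2 -0.14 ± 0.412, adjusted p = 0.985). The receptor genes Tnfrsf1a and Tnfrsf1b differed by 0.08 ± 0.112 and 0.18 ± 0.285. Interferon scores were 2.27 ± 0.366 under anti-TNF and 2.27 ± 0.417 under isotype, and 0 of 35 lists moved, with 0 at an unadjusted permutation p under 0.05, 6 by camera with a preset correlation and 0 with an estimated one. Limma called 0 of 14700 genes, with 804 at an unadjusted p under 0.05. Weighting each library in limma gave 2938 calls, but 9 of 20 shuffles of the labels gave calls as well, up to 6846. The weights were estimated anew for each shuffle. With muscle and epidermis scores as covariates 3 genes were called. The clock score was 0.612 ± 0.361 under anti-TNF and 1.22 ± 0.436 under isotype, a difference of -0.61 (permutation p = 0.00069, adjusted p = 0.00138). It was -0.50 in run 2 (2 against 1 library), -1.15 in run 3 (5 against 4) and -0.29 in run 5 (6 against 5). The clock genes were listed after the gene results were seen. The mouse numbers of these 2 groups do not overlap, so treatment and order of handling are not separated.

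Genes of the circadian clock differed between anti-IL-6 and isotype paws. Mouse numbers run in blocks by group, from anti-IL-6 over anti-TNF, combination and isotype to no CIA, so treatment and any order of handling are not separated. Dbp, a transcription factor whose messenger RNA oscillates strongly over the day, had 18.0 ± 10.7 FPKM under anti-IL-6 and 64.4 ± 22.1 under isotype (n = 13 each, log2 -1.90 ± 0.248, limma adjusted p = 5.64e-06). Its relative Tef was lower by a log2 difference of -0.86, the clock repressors Nr1d1 and Nr1d2 by -0.84 and -0.73, and Per3 by -0.77 (adjusted p = 2.18e-05, 0.00683, 5.06e-05 and 7.02e-05). In the other direction, Npas2, a partner of the clock activator Arntl, was higher by 0.67, and Nfil3, a repressor that opposes Dbp, by 0.74 (adjusted p = 0.00335 each). Outside the clock, the AP-1 transcription factor Fosl1 was higher by 0.85, the TWEAK receptor gene Tnfrsf12a by 0.51 and the orphan receptor gene Gprc5a by 0.49 (adjusted p = 0.00955, 0.00335 and 0.00335). Of the 13 anti-IL-6 libraries, 13 lay on the side of the change relative to the isotype mean for Dbp, Per3, Nr1d2, Npas2, Nfil3, Fosl1 and Tnfrsf12a, 12 for Tef and Nr1d1, and 11 for Gprc5a. Dbp (ENSMUSG00000059824.12) lies on chromosome 7 (45705088 to 45710203), Tef on chromosome 15 (81802421 to 81826863), Npas2 on chromosome 1 (39193731 to 39363236) and Nfil3 on chromosome 13 (52967209 to 52981073).

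Limma called 108 genes higher and 32 lower between anti-IL-6 and isotype. Of 20 clock genes, a list written after these results were seen and so not independent evidence, 11 were among the 140 calls (one-sided Fisher's exact test, p = 6.13e-18). The clock score was 0.0437 ± 0.452 under anti-IL-6 and 1.22 ± 0.436 under isotype, a difference of -1.18 (permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 0.0001 over 10 comparisons). Within index runs 2, 4 and 5 the difference was -0.86 (4 against 1 library), -1.75 (8 against 1) and -0.97 (1 against 5). All 10 genes named here were called in each of 26 fits that left out a library. The number of calls moved to 220 without anti-IL-6 replicate 7, and to 50, 93, 74 and 66 without anti-IL-6 replicates 9, 10, 11 and 13, and to 67, 67 and 68 without isotype replicates 1, 6 and 8. It was 20 with index run as a covariate, 446 with muscle and epidermis scores, 245 with median-of-ratios scaling, 231 with the compared groups alone, 591 with a weight per library, 55 with no filter and 43 without the 2 least correlated libraries. With the clock score, which is built from several of the called genes, it was 0, while the median size of the log2 difference of the 140 genes went from 0.24 to 0.19 and the median error from 0.0571 to 0.0798.

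None of the 35 lists moved between anti-IL-6 and isotype, and 1, cell cycle genes, had an unadjusted permutation p under 0.05 (difference 0.20, p = 0.0124, adjusted p = 0.435). Camera called 8 with a preset correlation and 0 with an estimated one. Il6 had 4.24 ± 5.43 FPKM under anti-IL-6 (log2 0.59 ± 0.412 against isotype, limma adjusted p = 0.576). Its receptor genes Il6ra and Il6st differed by -0.03 ± 0.087 and 0.04 ± 0.135. Neutrophil scores were 2.63 ± 1.06 under anti-IL-6 and 2.31 ± 0.836 under isotype. Skeletal muscle scores were 8.15 ± 1.33 and 8.88 ± 1.22 (permutation p = 0.159, adjusted p = 0.777), with 20 of 20 members lower and 0 past the test.

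**Figure D2:**
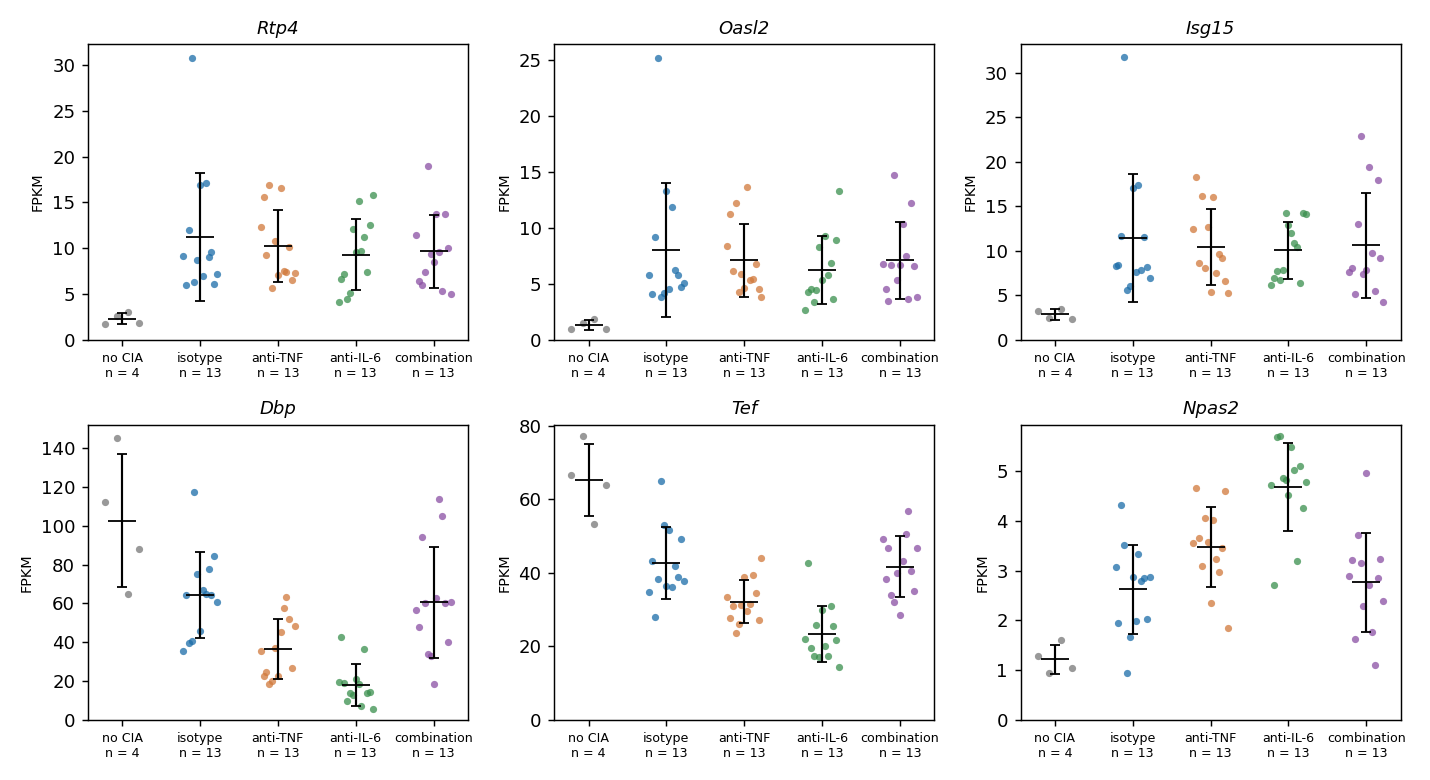
FPKM of Rtp4, Oasl2, Isg15, Dbp, Tef and Npas2 per library in the 5 groups; points are mice and bars the mean ± SD. The interferon-induced genes in the upper panels are low in the 4 no CIA mice, and Dbp is lowest under anti-IL-6 with a mean of 18.0 FPKM.

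No gene passed the test between the combination group and isotype. Dbp had 60.5 ± 28.6 FPKM in the combination group against 64.4 ± 22.1 under isotype, and Tef 41.7 ± 8.18 against 42.6 ± 9.76. Rtp4 had 9.64 ± 4.01 and 11.2 ± 6.98 FPKM. Tnf differed by a log2 value of 0.02 ± 0.172 and Il6 by -0.33 ± 0.412 (adjusted p = 1.00 each). Limma called 0 genes, with 850 at an unadjusted p under 0.05, and 0 of 35 lists moved, with 0 at an unadjusted permutation p under 0.05, 2 by camera with a preset correlation and 0 with an estimated one. The clock score differed by -0.11 (permutation p = 0.538), with 0.27 in run 2 (4 against 1 library), -0.67 in run 3 (4 against 4), -0.47 in run 4 (4 against 1) and -0.76 in run 5 (1 against 5).

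The combination group and anti-TNF alone also had no gene past the test. Dbp had 60.5 ± 28.6 FPKM in the combination group and 36.5 ± 15.4 under anti-TNF alone, Spon2 23.8 ± 10.8 and 34.1 ± 17.2, and Il6 1.15 ± 1.87 and 1.499 ± 2.20. The interferon scores were 2.24 ± 0.340 and 2.27 ± 0.366. Limma called 0 genes, with 160 at an unadjusted p under 0.05, and 0 lists moved, with 0 at an unadjusted permutation p under 0.05, 13 by camera with a preset correlation and 0 with an estimated one. Weighting each library gave 1 gene call. The clock score was higher in the combination group by 0.50 (permutation p = 0.00517, adjusted p = 0.00739), with 0.78 in run 2 (4 against 2 libraries), 0.48 in run 3 (4 against 5) and -0.48 in run 5, where 1 combination library met 6.

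Output genes of the clock were higher in the combination group than under anti-IL-6 alone. Dbp was higher in the combination group than under anti-IL-6 by a log2 difference of 1.73, Tef by 0.84, Nr1d1 by 0.82, Per3 by 0.63 and Nr1d2 by 0.59 (limma adjusted p = 4.60e-05, 4.60e-05, 0.0194, 0.00414 and 0.00414). Fosl1 was lower by -0.85, Nfil3 by -0.65 and Npas2 by -0.62 (adjusted p = 0.0262, 0.0288 and 0.0162). Akirin1, a nuclear protein, and Rrs1, a ribosome assembly factor, were lower by -0.30 and -0.28 (adjusted p = 0.0381 each). Il6 differed by -0.91 ± 0.412 (adjusted p = 0.398).

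Limma called 9 genes higher and 6 lower between combination and anti-IL-6, and 8 of these 15 were among the 20 clock genes. The count was 3 and 0 with the compared groups alone, 5 and 2 with no filter, 5 and 1 without the 2 least correlated libraries, 17 and 11 with muscle and epidermis scores, and 0 with the clock score. The clock score was higher by 1.07 (permutation p = 2e-05, adjusted p = 0.0001), with 1.14 in run 2, 1.28 in run 4 and 0.21 in run 5, which held 1 library of each group. The number of calls was 23 without anti-IL-6 replicate 7, 7 without anti-IL-6 replicate 4 or 13, 8 without anti-IL-6 replicate 9 or 12 or combination replicate 8 or 13, and 9 without combination replicate 1 or 10. Across the 26 fits that left out a library, Dbp, Tef, Per3, Nr1d2 and Npas2 were called in 26, Nr1d1 in 22, Fosl1 in 15, Nfil3 in 13, Akirin1 in 10 and Rrs1 in 10. Of 35 lists 0 moved, with 2 at an unadjusted permutation p under 0.05: cell cycle genes (difference -0.27, p = 0.00207, adjusted p = 0.0725) and immediate early genes (-0.35, p = 0.0236, adjusted p = 0.413). Skeletal muscle scores were 9.08 ± 1.14 in the combination group against 8.15 ± 1.33 (permutation p = 0.0692, adjusted p = 0.656). Camera called 15 with a preset correlation and 0 with an estimated one.

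The antibodies against TNF and IL-6 were also compared with each other. No gene passed the test. Dbp had 36.5 ± 15.4 FPKM under anti-TNF and 18.0 ± 10.7 under anti-IL-6, and Il6 1.499 ± 2.20 and 4.24 ± 5.43 (log2 -0.73 ± 0.412, limma adjusted p = 0.976). Limma called 0 genes, with 688 at an unadjusted p under 0.05, 17 with a weight per library and 1 with the neutrophil score as a covariate. Immediate early genes were the 1 list of 35 with an unadjusted permutation p under 0.05 (difference -0.33, p = 0.0408, adjusted p = 0.993), and camera called 11 with a preset correlation and 0 with an estimated one. The clock score was 0.612 ± 0.361 under anti-TNF and 0.0437 ± 0.452 under anti-IL-6 (permutation p = 0.00177, adjusted p = 0.00295), and higher under anti-TNF by 0.36 in run 2 (2 against 4 libraries) and 0.69 in run 5 (6 against 1).

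The 4 arthritic groups form a layout in which the difference with and without anti-IL-6 can be compared in the presence and absence of anti-TNF. Antibody dose was not matched: isotype and anti-TNF mice received 30 mg/kg, anti-IL-6 mice 10 mg/kg, and combination mice 30 and 10 mg/kg. The labels give no isotype antibody in the treated groups. Group means of clock genes departed from the sum of the single differences, in groups whose mouse numbers do not overlap but for 2 mice. In the order of these numbers, mean clock scores rose from 0.0437 under anti-IL-6 over 0.612 under anti-TNF and 1.11 in the combination group to 1.22 under isotype. A steady rise with mouse number would by itself give a positive departure of this score. An order of handling is therefore not separated from a joint effect of the antibodies. For Dbp the difference was higher by a log2 value of 2.58 in the presence of anti-TNF than in its absence, for Tef by 1.22, for Ciart, a clock-associated repressor, by 1.18, for Nr1d1 by 1.09 and for Per3 by 1.06 (limma adjusted p = 1.78e-05, 2.08e-05, 0.0404, 0.0296 and 0.000204). Of 52 fits that left out a library, Ciart was called in 22 and Nr1d1 in 41, with adjusted p up to 0.0744 for Ciart without isotype replicate 5 and 0.0581 for Nr1d1 without anti-TNF replicate 4. The value was negative for Nfil3 (-0.95), Npas2 (-0.94) and Arntl (-0.76), and smaller in size for Jmjd6, a lysyl hydroxylase (-0.38), and Leo1, a transcription elongation factor (-0.37), with adjusted p = 0.0186, 0.00562, 0.0186, 0.0115 and 0.00562. Limma found 9 genes with a positive and 8 with a negative departure, and 10 of the 17 were clock genes. Median-of-ratios scaling gave 18 positive and 24 negative, the count was 35 without anti-TNF replicate 7, and it was 63 with muscle and epidermis scores, 2758 with a weight per library, 11 without the 2 least correlated libraries and 0 with the clock score as a covariate. None of the 35 list scores departed from additivity (lowest permutation adjusted p = 0.519). Cell cycle genes had an unadjusted permutation p under 0.05 (departure -0.288, p = 0.0278). Skeletal muscle markers had the value 1.26 (permutation p = 0.0768).

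**Figure D3:**
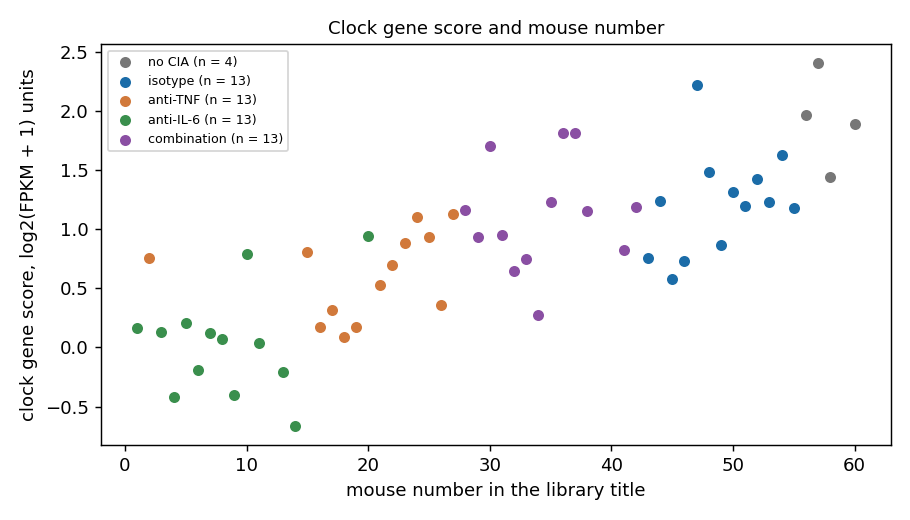
Clock gene score of each library, in log2(FPKM + 1) units, against the mouse number in its title; colours are the 5 groups. Mouse numbers run in blocks by group, with anti-IL-6 lowest in number and no CIA highest, and the mean score goes from 0.0437 under anti-IL-6 to 1.93 without CIA.

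Each treated group was set against mice without CIA to see which differences from no CIA were measurable after treatment had ended. Interferon-induced genes were higher in all 3. Oas1a was higher than in no CIA by 1.81 under anti-TNF, 1.61 under anti-IL-6 and 1.74 in the combination group (limma adjusted p = 0.00294, 0.00448 and 0.0161), and Rtp4 by 1.71, 1.56 and 1.62 (adjusted p = 0.00345, 0.00448 and 0.0161). Plac8, a leukocyte protein, and Spon2, a secreted matrix protein, were higher by 2.33 and 1.88 under anti-TNF and by 2.09 and 2.16 under anti-IL-6. Clock genes were lower: Dbp by -1.52 under anti-TNF and -2.57 under anti-IL-6 (adjusted p = 0.0266 and 1.02e-05), and Per3 by -1.10, -1.45 and -0.82 in the 3 groups (adjusted p = 0.00046, 2e-07 and 0.0199). Mouse numbers of the no CIA group do not overlap those of the treated groups, so an order of handling is not separated from these clock differences. The complement genes C2 and C4b were higher under anti-TNF by 0.92 and 0.68. Ccl8, a monocyte chemokine, the adhesion molecule Icam1, the class II gene H2-DMb1 and the venular receptor gene Ackr1 were higher under anti-IL-6 by 1.92, 1.13, 1.05 and 0.70, and Pck1, a gluconeogenic enzyme, was lower by -1.17. Across the 17 fits that left out a library, several of these calls were lost in most. Under anti-IL-6 Ccl8 was called in 9, H2-DMb1, Ackr1 and Plac8 in 7, and Icam1 and Pck1 in 6. Without no CIA replicate 2 adjusted p was 0.215 for Ccl8, 0.199 for Icam1, 0.217 for H2-DMb1, 0.197 for Plac8 and 0.273 for Pck1, and without no CIA replicate 4 it was 0.198 for Ackr1. C2, C4b, Plac8 and Dbp under anti-TNF, and Oas1a, Rtp4 and Per3 in the combination group, were called in 14 of 17. For Dbp under anti-TNF limma's adjusted p was 0.231 without no CIA replicate 2.

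In lists, the interferon score was higher than without CIA by 0.97 under anti-TNF, 0.88 under anti-IL-6 and 0.93 in the combination group (exact permutation p = 0.00042 each, the smallest possible, adjusted p = 0.0147). With an estimated correlation, camera gave it adjusted p = 0.201, 0.371 and 0.0492. Under anti-TNF 3 lists were higher, which also included complement genes (0.80) and endothelial markers (0.44). In the combination group 4 were higher, with monocyte and macrophage markers (0.84), complement genes (0.64) and class II genes (0.63), for which camera with an estimated correlation gave adjusted p = 0.419 each. Under anti-IL-6 20 lists were higher and 1, adipocyte markers, was lower (-0.67, adjusted p = 0.0426). Those higher included matrix-degrading enzymes (1.54), mature neutrophil markers (1.44), fibrillar matrix genes (1.34), genes responding to IL-6 and STAT3 (1.27) and osteoclast markers (1.14), with exact permutation adjusted p = 0.0347, 0.0347, 0.0347, 0.0347 and 0.0364. Camera with an estimated correlation called none of the anti-TNF or anti-IL-6 lists (lowest adjusted p = 0.201 and 0.371). Scoring lists by the median of members gave 1 list higher under anti-TNF and 9 under anti-IL-6, and median-of-ratios scaling gave 10 under anti-TNF. The difference between treated groups in number of lists was not tested, and none of the lists differed between treated groups themselves.

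Limma called 70 genes higher and 11 lower than no CIA under anti-TNF, 59 and 23 under anti-IL-6, and 21 and 2 in the combination group. Median-of-ratios scaling gave 77 and 50 under anti-IL-6. With pseudocount 10 the splits were 20 and 12, 10 and 19, and 0 and 2 in these groups, and with no filter 51 and 42, 33 and 48, and 16 and 20. With the neutrophil score as a covariate, whose group means are higher in the treated groups than in no CIA, the counts fell to 7, 17 and 3. The anti-TNF count was 223 without anti-TNF replicate 7, 167 without anti-TNF replicate 13, and 26, 20 and 7 without no CIA replicates 1, 2 and 4. The anti-IL-6 count was 31, 17, 39 and 18 without no CIA replicates 1, 2, 3 and 4, was 149 and 132 without anti-IL-6 replicates 2 and 5, and was 50, 48, 49, 45 and 48 without anti-IL-6 replicates 4, 6, 8, 12 and 13. The combination count was 0 without no CIA replicate 1, 2 or 4 and 13 without no CIA replicate 3, and was 15, 50, 13, 15 and 45 without combination replicates 1, 3, 4, 6 and 10. With the clock score as a covariate each of the 3 counts was 0, while the median size of the log2 difference of the called genes went from 0.95 to 0.52 under anti-TNF, from 0.95 to 0.24 under anti-IL-6 and from 1.11 to 0.86 in the combination group. No index run held libraries of both a treated group and no CIA. With run as a covariate, linked through the 2 isotype libraries of run 1, the counts were 3264, 1608 and 118. Clock scores of the 3 treated groups, in that order, differed from no CIA by -1.31, -1.88 and -0.82 (exact permutation adjusted p = 0.00105, 0.00105 and 0.00840).

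A signature of genes that differ between isotype and no CIA was used to ask whether treated paws lay closer to no CIA. Genes were chosen between the 7 odd-numbered isotype libraries and no CIA, which gave 11 higher and 1 lower gene, and scores were compared with the 6 isotype libraries not used to choose them. The score was 1.61 ± 0.617 in those isotype mice, 1.82 ± 0.435 under anti-TNF, 1.57 ± 0.548 under anti-IL-6 and 1.60 ± 0.631 in the combination group, against -0.53 ± 0.568 in the 4 mice without CIA, on which the genes were chosen. It is the mean of the higher genes minus that of the lower, so the 1 lower gene weighed as much as the 11 higher together. Differences from isotype were 0.20, -0.04 and -0.02 (exact permutation p = 0.414, 0.895 and 0.960), each within the spread between mice. Without no CIA replicate 1 they were 0.06, -0.09 and 0.01, and without replicate 2 they were 0.04, -0.12 and 0.01, so the sign for the combination turned. Neither of these choices held a lower gene, so their scores are means of higher genes alone. Without replicate 4 no gene was chosen. Genes chosen with the last 7 isotype libraries, all of them higher, gave 0.22, 0.08 and 0.12. The even-numbered libraries gave 0 genes without scaling, so no score could be made the other way round from them. With median-of-ratios scaling they gave 8 genes, all of them higher, and differences of 0.13, -0.01 and 0.11.

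Fold changes of the 3 treatments against the same isotype mice were correlated across 14700 genes, which are not independent replicates. Pearson's r was 0.63 between anti-TNF and anti-IL-6, 0.51 between anti-TNF and combination and 0.22 between anti-IL-6 and combination. Unchanged groups were simulated by shuffling residuals over all 52 arthritic libraries. Their shared control group was thus simulated too, and was not the real isotype mice. These simulations gave mean r of 0.47, 0.45 and 0.44, with ranges from -0.14 to 0.86, from -0.34 to 0.86 and from -0.26 to 0.83. Covariances were 0.0135, 0.00817 and 0.00420 against simulated means of 0.0112, 0.0107 and 0.00998. With the isotype mice split so that no library was shared, r was -0.19 or 0.19 for the first pair, 0.03 or -0.39 for the second and 0.17 or -0.54 for the third. No gene was called in 2 of the 3 comparisons, of which only anti-IL-6 against isotype had calls.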

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

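The test for a non-additive effect and the test for a library apart from its group were fixed before the data were examined, while the tests of explanations for the clock genes were chosen after the result was seen. The rule that leaves an alike effect of IL-6 blockade open, joined by an order of handling, when mouse numbers do not overlap was set after its value was seen. The prediction first written counted a higher combination score against an alike effect.

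In limma's interaction test 17 genes departed from additivity between groups whose mouse numbers run in blocks. A steady rise of the clock score with these numbers would also give a positive departure of that score. For clock genes the test thus does not separate an order of handling from a joint effect of the antibodies. The log2 departure from the sum of the single effects was 2.58 for Dbp, 1.22 for Tef, 1.18 for Ciart, 1.09 for Nr1d1 and 1.06 for Per3. It was -0.95 for Nfil3, -0.94 for Npas2, -0.76 for Arntl, -0.38 for Jmjd6 and -0.37 for Leo1. Dbp, Tef, Per3, Nfil3, Npas2, Arntl, Jmjd6 and Leo1 were called in 52 of 52 fits that left out a library, Nr1d1 in 41 and Ciart in 22. Of 100 splits of the libraries, the real one included, 2 gave 17 calls or more (share 0.0367 adjusted over 11 comparisons). The other of these gave 820 calls and may point to a structure of the samples. Shuffling libraries between groups removes every group difference at once and ignores the blocks of mouse numbers. The splits therefore do not test additivity by itself, and chance is not excluded by them. The count was 35 without anti-TNF replicate 7.

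Clock genes differed between anti-IL-6 and isotype, with a clock score difference of -1.18. Tissue make-up and inflammation of the paw as the whole cause is argued against by a difference of -1.09 (SE 0.164, 95% interval -1.42 to -0.762) with muscle, epidermis and neutrophil scores as covariates. An effect of IL-6 blockade that is alike with and without TNF blockade would lower the combination score below that of anti-TNF. As the whole cause it is argued against, since the combination score was higher by 0.497 (permutation p = 0.00517, adjusted p = 0.00739). The difference was 0.776 in run 2, 0.479 in run 3 and -0.476 in run 5, where 1 combination library met 6. Mouse numbers of these 2 groups do not overlap, so an alike effect joined by an order of handling is left open. A time of dissection that followed the mouse number cannot be told apart from treatment, because mouse numbers run in blocks by group, and within groups the clock score and mouse number had r = 0.219 (permutation p = 0.118) and rho = 0.227 (permutation p = 0.118, adjusted p = 0.235 over 14 relations). An effect of the antibodies on the clock may therefore be one explanation and the order of dissection another, and the time of dissection is not given in the sources used here.

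Of 76 values tested in the 4 no CIA mice, 2 had a library apart from the others, where chance gives about 1 in 20. Il6ra in no CIA replicate 3 had a log2(FPKM + 1) of 2.48 against 2.67 to 2.69 in the others (gap over range 0.874). Gprc5a in no CIA replicate 4 had 2.12 against 1.73 to 1.75 (gap over range 0.928). The miRBase hairpins, which entered no comparison, had a summed FPKM of 1.97 ± 0.997 in 13 isotype mice and 0.623 ± 0.529 in 4 mice without CIA (exact permutation p = 0.0244).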

How the results depend on the processing

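Median-of-ratios scaling, the weight per library, leaving out the 2 least correlated libraries, the clock and neutrophil covariates, and the list tests without an isotype library were chosen after the data were seen, and the other alternatives before. No paired analysis was possible because replicate numbers follow the order of deposition and pair no mice. DESeq2, its size factors and count-based weights were not run, because the file holds FPKM. Of 74 called results for named genes, 74 were still called with a weight per library, with pseudocount 0.1 and with median-of-ratios scaling, 62 with index run, 62 with muscle and epidermis scores, 59 with no filter, 58 without the 2 least correlated libraries, 54 with the compared groups alone, 47 with the neutrophil score, 44 with pseudocount 10 and 0 with the clock score. The 13 that turned direction did so with the clock score, which is built from such genes. A weight per library also gave calls in 9 of 20 shuffles of the anti-TNF and isotype labels, so keeping all 74 under it says little. Of 264 values of uncalled drug targets, 37 turned direction and 5 were newly called. Depth cannot be rebuilt as counts, and 4 mice without CIA limit each comparison with them. Except where the construction shows it, the cause of a change was not tested.

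The numbers of called genes by limma are given in the order isotype, anti-TNF, anti-IL-6 and combination against no CIA where all are named. With pseudocount 0.1 they were 66 for isotype, 146 for anti-IL-6 and 59 for combination against no CIA. With pseudocount 10 they were 5, 32, 29 and 2. With no filter they were 35 for isotype and 36 for combination against no CIA, 55 for anti-IL-6 against isotype and 7 for combination against anti-IL-6. With index run as a covariate they were 2744, 3264, 1608 and 118, and 20 for anti-IL-6 against isotype. With muscle and epidermis scores they were 76, 52, 35 and 36, 3 for anti-TNF and 446 for anti-IL-6 against isotype, 28 for combination against anti-IL-6 and 63 for the non-additive effect, and 3 genes were called in more than 1 comparison against isotype. With the compared groups alone they were 35 for isotype and 37 for anti-IL-6 against no CIA, 231 for anti-IL-6 against isotype and 3 for combination against anti-IL-6. With median-of-ratios scaling they were 67 for isotype, 127 for anti-IL-6 and 35 for combination against no CIA, 245 for anti-IL-6 against isotype and 42 for the non-additive effect.

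With a weight per library the numbers were 1562, 6971, 4132 and 388 against no CIA, 2938 for anti-TNF and 591 for anti-IL-6 against isotype, 1 for combination against anti-TNF, 17 for anti-TNF against anti-IL-6 and 2758 for the non-additive effect, and 364 genes were called in more than 1 comparison against isotype. For anti-TNF against isotype, 6 of 20 shuffles of the labels gave as many calls under such weights. Without anti-IL-6 replicates 13 and 6, whose median correlations with other libraries were 0.895 and 0.938, they were 49, 137, 32 and 36, 43 for anti-IL-6 against isotype, 6 for combination against anti-IL-6 and 11 for the non-additive effect. With the neutrophil score they were 11, 7, 17 and 3, and 1 for anti-TNF against anti-IL-6. With the clock score limma called 0 in each comparison that had calls, and unadjusted p under 0.05 was reached by 546, 344, 167 and 293 genes against no CIA, 1883 for anti-IL-6 against isotype, 948 for combination against anti-IL-6 and 1312 for the non-additive effect.

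Leaving out 1 library at a time gave 0 to 59 calls for isotype, 7 to 223 for anti-TNF, 17 to 149 for anti-IL-6 and 0 to 50 for combination against no CIA, 50 to 220 for anti-IL-6 against isotype, 7 to 23 for combination against anti-IL-6, 12 to 35 for the non-additive effect, and 0 in 26 of 26 fits for each comparison with 0 calls. Lists that moved between isotype and no CIA were 0 to 4 without a no CIA library and 2 to 17 without an isotype library. With 1 no CIA library left out, replicate 1, 2 or 3, the signature difference was 0.042 to 0.195 for anti-TNF, -0.119 to -0.050 for anti-IL-6 and -0.021 to 0.015 for combination, the last at 0.015 and 0.014 without no CIA replicates 1 and 2. No value could be had without no CIA replicate 4, or, on the values as deposited, from the even-numbered or first 6 isotype libraries, since 0 genes passed. With genes from the last 7 isotype libraries the difference was 0.084 for anti-IL-6 and 0.115 for combination, and with median-of-ratios scaling and genes from the even-numbered libraries 0.108 for combination. Camera with a preset correlation called 28 lists for isotype against no CIA, 6, 8 and 2 for anti-TNF, anti-IL-6 and combination against isotype, 13 for combination against anti-TNF, 15 for combination against anti-IL-6 and 11 for anti-TNF against anti-IL-6, and with an estimated correlation 0 for each of these 7, with 1 at an unadjusted p under 0.05 for isotype against no CIA, 1 for combination against anti-TNF and 0 for the other 5. With the isotype mice split so that no library was shared, the correlation of fold changes across genes was -0.190 and 0.187 for anti-TNF and anti-IL-6, 0.0324 and -0.394 for anti-TNF and combination, and 0.174 and -0.537 for anti-IL-6 and combination.

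Log2 differences that turned direction with the neutrophil score were Tnf -0.005, Il6ra -0.061, Tnfrsf1b -0.029, Il6 -0.046 and Tnfrsf1a -0.003 for isotype against no CIA, Il6st -0.056 and Tnfrsf1b -0.007 for anti-TNF, and Il6st -0.067 and Tnfrsf1b -0.060 for anti-IL-6 against isotype. With the clock score they were Il6st -0.181, Tnfrsf1b -0.255 and Tnfrsf1a -0.033 for anti-TNF against isotype, and Il6st -0.360, Tnf -0.029, Tnfrsf1b -0.652, Il6 -0.547, Tnfrsf1a -0.031, Nfil3 -0.027, Npas2 -0.022 and Nr1d1 0.046 for anti-IL-6 against isotype. They were Tnf -0.001 and Tnfrsf1a -0.012 for combination against isotype, Per3 -0.037, Nfil3 0.046 and Npas2 0.007 for combination against anti-IL-6, Dbp 0.357 for anti-TNF and Dbp 0.117 and Ciart 0.165 for anti-IL-6 against no CIA, and Ciart -0.355, Nr1d1 -0.169, Nfil3 0.144 and Npas2 0.045 for the non-additive effect. With muscle and epidermis scores they were Il6st -0.096, Tnfrsf1b -0.072 and Tnfrsf1a -0.011 for anti-TNF, and Il6st -0.142, Tnf -0.005 and Tnfrsf1b -0.198 for anti-IL-6 against isotype. Without the 2 least correlated libraries they were Il6st -0.072 and Tnfrsf1b -0.039 for anti-IL-6 against isotype. With a weight per library they were Il6ra 0.021 and Il6 0.118 for anti-TNF and Tnfrsf1b 0.018 for combination against isotype. With index run they were Il6 0.231 for anti-TNF, Il6ra 0.038 for anti-IL-6, and Il6st 0.011 and Tnfrsf1b 0.191 for combination against isotype. Median-of-ratios scaling gave Il6ra -0.004 for isotype against no CIA and Tnfrsf1b 0.001 for combination against isotype, and pseudocount 0.1 gave Tnf -0.002 for combination against isotype.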

Other observations

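The tests of explanations, the bar for the count of splits, the clock gene list and the relations between scores in this part were chosen after the results were seen. The adjustment of the split shares, and the rule that leaves index run open when under 3 libraries of a group share a run with the other, were set after the values were seen: the bar first written, 80% of genes still called, was met.

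Paws differed in tissue content within groups. Per unit of skeletal muscle score, the fibrillar matrix score changed by -0.448 ± 0.0843 (SE), mature neutrophil markers by -0.403 ± 0.0882, osteoclast markers by -0.371, osteoblast markers by -0.333, cartilage markers by -0.223 and adipocyte markers by 0.236 ± 0.0364. Between isotype and no CIA, marrow granulocyte precursor markers differed by 1.30, erythroid markers by 0.95, osteoclast markers by 0.83, cartilage markers by 0.73, Schwann cell and nerve markers by -0.32 and oxidative phosphorylation genes by -0.38 (exact permutation adjusted p = 0.0968, 0.102, 0.102, 0.111, 0.111 and 0.245), and none of these passed the correction.

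Mice with higher neutrophil scores had higher interferon scores within the 4 arthritic groups (n = 52, 14 relations in the family). Pearson's r was 0.777 and Spearman's rho 0.772 (permutation p = 1e-05 each, the smallest possible, adjusted p = 7e-05), and r was 0.751 without the 2 libraries farthest from the median. Within runs 2, 3, 4 and 5 r was 0.656, 0.931, 0.773 and 0.608 (permutation p = 0.0445, 0.0002, 0.0053 and 0.0702). Interferon and muscle scores had r = -0.383 (permutation p = 0.00653, adjusted p = 0.0253) and rho = -0.326 (permutation p = 0.0232), r = -0.386 without the 2 farthest, and -0.277, -0.637, -0.418 and -0.415 within those runs. Clock and neutrophil scores had r = -0.343 (permutation p = 0.0150, adjusted p = 0.0420) and rho = -0.337 (permutation p = 0.0186). Without the 2 farthest libraries r was -0.247 and no longer past the threshold (adjusted p = 0.216), and within runs 2, 3, 4 and 5 it was 0.0204, -0.480, -0.741 and -0.309 (permutation p = 0.958, 0.0863, 0.0096 and 0.401). Clock score and mouse number had r of 0.439, 0.368, -0.557 and 0.509 within those runs (permutation p = 0.166, 0.219, 0.0824 and 0.136), and r was 0.188 without the 2 mice numbered outside their group.

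Interferon response genes were higher in mice with CIA than without. With run as a covariate, 22 of the 23 genes called between isotype and no CIA were still called. Only 2 isotype libraries shared a run with no CIA, and these had the highest neutrophil scores of their group (3.76 and 3.50). Their interferon scores were 3.36 and 2.62, against 1.205 to 1.429 in no CIA, which argues against index run as the whole cause for these 2 libraries. For isotype libraries of other runs, index run is left open. Neutrophil content as the whole cause is argued against by a score difference of 0.631 (95% interval 0.364 to 0.899) that was left of 0.967 with the neutrophil score as a covariate. With the clock score as a covariate, 0.715 (95% interval 0.322 to 1.11) was left, and gene calls fell to 0, while over the 23 called genes the median size of the log2 difference went from 1.02 to 0.82 and the median error from 0.222 to 0.228. The disease itself may be the source, and immunisation, antibody injection and handling, in which mice without CIA differ from the rest, stay open.

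A few arbitrary groupings of the libraries gave many calls, while the median of the other splits was 0 in each of 11 comparisons. Of 100 splits, the real one included, 1 gave at least the real 23 calls between isotype and no CIA (highest other 17), 4 at least 140 between anti-IL-6 and isotype (3107), 2 at least 15 between combination and anti-IL-6 (3421), 2 at least 81 between anti-TNF and no CIA (265), and 1 at least 82 and 23 between anti-IL-6 or combination and no CIA (highest other 1 each). Each share is under 0.05, so few shuffles of the libraries reached the real count. Adjusted over 11 comparisons the share for anti-IL-6 against isotype is 0.0629 and the others 0.0367, so for that count chance stays open. The shuffles ignore index runs and the blocks of mouse numbers, and 100 splits cannot give a share under 0.01. For the 4 comparisons with 0 calls any split reaches the count, so 100 of 100 is no test, and the highest others were 2476 for anti-TNF and 2084 for combination against isotype, 974 for anti-TNF against anti-IL-6 and 5 for combination against anti-TNF.

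The splits with many calls may point to a structure of the samples. If only the share of muscle varied between paws, neutrophil and epidermis scores would fall alike per unit of muscle score. The neutrophil score fell more (difference -0.376, 95% interval -0.651 to -0.102), which argues against muscle share as the only tissue difference between paws. Muscle scores of the splits with many calls were not compared, so muscle share as their source is left open. Unequal arthritis within a group may be another source, with an SD of the neutrophil score 9.37 times as large in isotype as in no CIA mice (exact permutation p = 0.0492, adjusted p = 0.123 over 5 lists), and 4 mice without CIA are too few to decide it.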
